A study of Mus musculus with 6 samples.

How the data were processed

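Total RNA of mouse hearts was extracted with a column kit, made into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The samples fall into 3 groups of 2 arrays. The deposited table holds 1 linear intensity per probe set and array; the submitters' processing notes name GCOS, whose version, background step and scaling are not given in the sources used here. Detection calls were not used here.

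The design written before the data were examined took the deposited signals as already scaled between arrays. The signals turned out not to be: 2%-trimmed means ran from 126 to 341, and the geometric means of 18 hybridization control probe sets from 654 to 1551. Brightness was ordered as untreated apoE-deficient, B6, treated, so it is confounded with group. The main analysis therefore used quantile normalization of the linear signals of 45037 non-control probe sets, then a pseudocount of 11.1 (the 25th percentile of all values) and log2. Quantile normalization, of log2 values, had been listed as an alternative beforehand. Trimmed-mean and spike-in scaling were added after the data were seen, and the unscaled values, the setting of the original design, became an alternative. The median of all log2 differences was -0.016 (treated minus untreated apoE-deficient), -0.0064 (untreated apoE-deficient minus B6) and -0.023 (treated minus B6) with quantile normalization. Spike-in scaling moved it to 0.18, 0.11 and 0.28, array medians centred to -0.13, 0.047 and -0.081, and no scaling to 1.13, -0.32 and 0.81. Changes are reported relative to quantile normalization. The brightest genes change sign between scalings, so their directions are given with the settings that turn them.

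Of 45101 probe sets, 64 controls were left out, and probe sets with a mean log2 value above the 40th percentile (4.99) were tested, 27022 in all. The given annotation of the array, which can be old, paired 34945 non-control probe sets with 1 gene symbol, 932 with several and 9160 with none; probe sets with several or none were not named. Symbols of 34741 were updated through their gene number with a gene table of assembly GRCm38.p6, used only for names, and no coordinates are given because no build is named. A gene is represented by its probe set with the highest mean, 13236 genes in all.

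Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) over all 6 arrays in 1 fit of 3 groups, with 3 residual degrees of freedom and 5.97 prior ones. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were fixed beforehand, 42 in number, of which 41 were tested with camera (preset correlation 0.01, at least 5 tested genes, adjusted over the lists of a comparison) and 1 holds sex-linked genes as a sample check. Camera was repeated with an estimated correlation. That setting also takes the 3 residual degrees of freedom of the fit. Its p-values can thus rise even where the estimate is below the preset 0.01. For white adipocyte markers in treated against untreated apoE-deficient arrays the estimate was -0.052, and the unadjusted camera p rose from 1.89e-09 to 0.00748. A call lost in that setting does not by itself show that the genes of a list are correlated. Some estimates did lie above the preset value, the highest at 0.26 for mitochondrial fatty acid oxidation and 0.17 for brown adipocyte markers. For such lists the p-values with the preset correlation can be too small. In addition, fry was run as a self-contained test. Fry asks whether a list's genes move one way on balance and does not compare the list with other genes.

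Named genes follow a rule fixed beforehand: the 12 highest and 12 lowest log2 differences that passed with no overlap between arrays, up to 4 members of each list with the smallest p, and a panel of heart and lipid genes. The text names fewer than the rule gives, and which of them to describe was chosen after the values were seen. Members named because a count of list members was 5 or fewer were chosen after their values were seen.

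The test was tried on simulated data drawn from the means and variances of the 27022 probe sets, with 200 changed. In the comparison of treated with untreated apoE-deficient arrays it recovered 26.9% of probe sets changed by 0.5 on the log2 scale, 68.7% of those changed by 1 and 83.3% of those changed by 2, and 8.46% of its calls were false. For untreated apoE-deficient against B6 the shares were 31.3%, 62.7% and 87.9%, with 9.70% of calls false, and for treated against B6 34.3%, 62.7% and 86.4%, with 11.6% false. The false share thus exceeded the nominal 5% in each. With 13236 simulated genes and 1 of 41 lists shifted by 0.3 on the log2 scale, camera called the shifted list in each comparison and 0 other lists. Genes were drawn independently there, so false list calls that come from correlated genes could not appear.

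Arrays of a group correlated with r = 0.987 (treated), 0.968 (untreated apoE-deficient) and 0.977 (B6) across log2 values. The 3'/5' signal ratio was 1.28 to 1.34 for actin and 0.853 to 0.923 for Gapdh. Over the 6 arrays, the normalized signal ran from 356 to 549 for Y-linked Eif2s3y, 63.0 to 127 for Kdm5d and 71.6 to 169 for Uty, and from 21.1 to 64.9 for Xist. Among lists that passed, 0 had a median or mean opposite to the test. Overlap of calls was compared with 100 simulations of unchanged groups. Alternatives were other pseudocounts, filters, scalings, variance models, a 2-group fit, other thresholds, a block for the replicate number, the mean of a gene's probe sets and leaving out each array in turn.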

Results

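Heart RNA of 3 groups of mice was hybridised to Affymetrix arrays, 2 arrays per group. The groups were apoE-deficient mice given rosiglitazone, which the labels call failing hearts, untreated apoE-deficient mice, and untreated B6 mice without the deficiency. ApoE is an apolipoprotein, a protein of the particles that carry cholesterol and triglyceride. Rosiglitazone is an antidiabetic drug that activates the nuclear receptor PPAR gamma. All mice were 8 months old and ate chow with 7% fat and 0.15% cholesterol, and the treated mice received 30 mg/kg per day for 2 months from an age of 6 months. The 2%-trimmed mean signals of the deposited table were 341 and 263 on the treated arrays, 126 and 130 on the untreated apoE-deficient arrays, and 175 and 149 on the B6 arrays, and precision is limited by the number of arrays. Values below are differences of log2 normalized signal ± SE from limma with n = 2 arrays per group, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Differences are on a log2(value + pseudocount) scale, which understates the change of genes with low signal. The labels do not say that the arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

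The Apoe signal checked the labels first. Apoe had a log2 level of 11.88 ± 0.04 (SD, n = 2) on the B6 arrays, 5.77 ± 0.75 on the untreated apoE-deficient arrays and 6.23 ± 0.04 on the treated arrays. The difference from B6 was -6.12 ± 0.27 in untreated (adjusted p = 6.45e-06) and -5.66 ± 0.27 in treated apoE-deficient hearts (adjusted p = 3.39e-06). Where the probes lie relative to the deleted part of the gene was not determined. The treated and untreated apoE-deficient arrays differed in Apoe by 0.46 ± 0.27 (adjusted p = 0.286), which did not pass, although it passed without untreated replicate 2 (0.99).

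**Figure D1:**
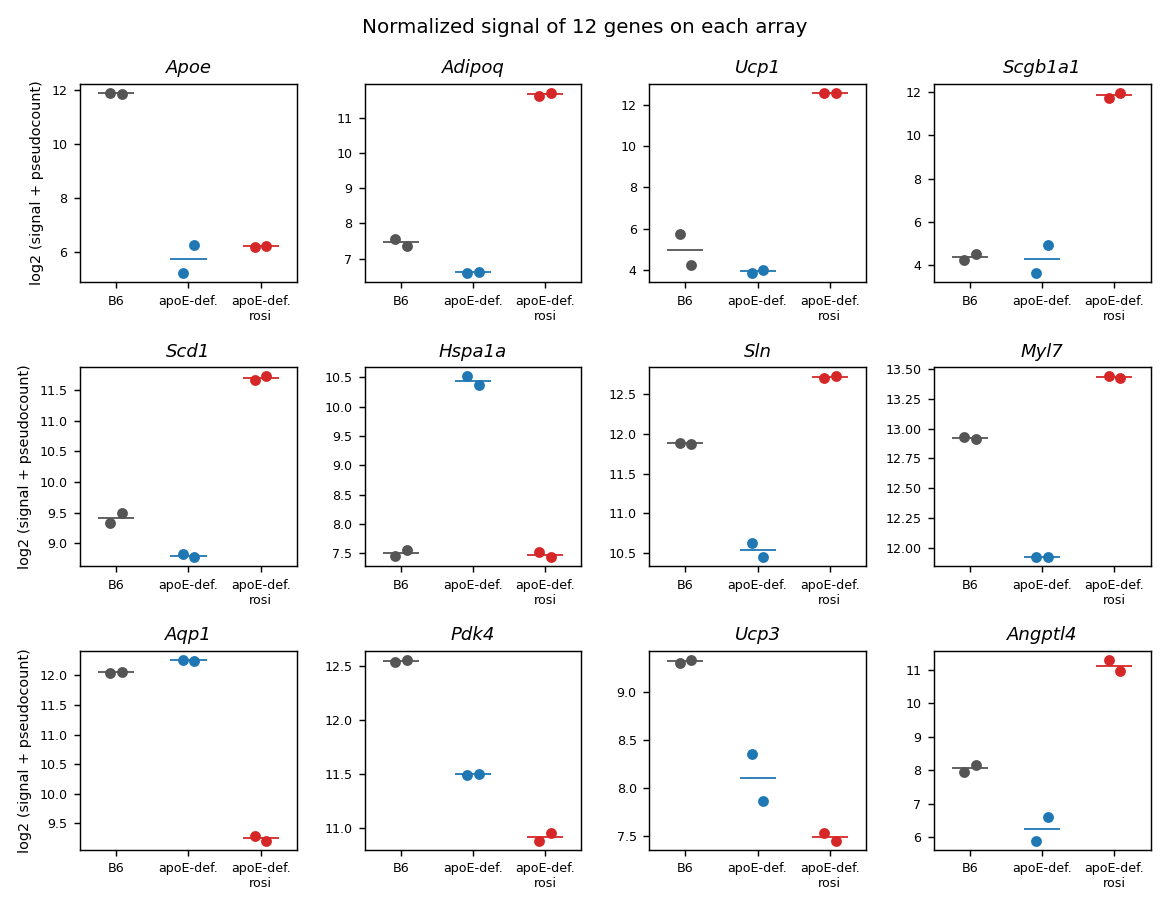
Log2 of normalized signal plus pseudocount (vertical axes, each with its own range that does not start at 0) for 12 genes on the B6 control, untreated apoE-deficient (apoE-def.) and rosiglitazone-treated apoE-deficient (rosi) arrays. Each point is 1 array and each line is the mean of 2 arrays. Hspa1a stood at 10.44 ± 0.10 (mean ± SD) on the untreated apoE-deficient arrays, against 7.48 ± 0.06 on the treated and 7.51 ± 0.07 on the B6 arrays.

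The first comparison asked what 2 months of rosiglitazone, with the failing state named in the labels, changed in apoE-deficient hearts. Of genes of fat cells and fat synthesis, 12 of 17 white adipocyte markers and 12 of 20 lipogenesis genes rose in the treated hearts and 1 and 4 fell (adjusted p = 0.149 and 0.207 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, rose by 5.09 ± 0.10 (adjusted p = 1.52e-08), Cidec, a lipid droplet protein, by 4.94 ± 0.18, and Scd1, a fatty acid desaturase, by 2.91 ± 0.07. The sources used here do not say whether fat was trimmed from the hearts, so the values of fat cell, brown fat and lipogenesis genes do not tell heart muscle from attached fat. Among transcripts that heart muscle does not normally make at high level, Ucp1, the uncoupling protein of brown fat, rose by 8.69 ± 0.39 and the airway secretory proteins Bpifa1 by 8.65 ± 0.25 and Scgb1a1 by 7.55 ± 0.36. Of 16 heat shock proteins 12 fell and 1 rose (adjusted p = 0.149 with an estimated correlation), with the inducible chaperones Hspa1a at -2.96 ± 0.10 and Hspa1b at -2.89 ± 0.10. The water channel Aqp1 fell by 3.0 ± 0.05 on the log2 scale (adjusted p = 5.72e-09), and the potassium channel Kcna5 changed by -2.30 ± 0.10.

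Of the 17 tested white adipocyte markers, 12 rose, 1 fell and 4 did not pass (13 higher and 1 lower adjusted over the list alone), Plin4 being the one lower (-0.55). White adipocyte markers had a median log2 difference of 1.11, with a camera adjusted p = 7.73e-08, and adjusted p = 0.149 with an estimated correlation. Car3, an adipocyte carbonic anhydrase, differed by 3.69 ± 0.06 and Cidea by 2.06 ± 0.05. The fatty acid carrier Fabp4, found in adipocytes and capillary endothelium, was higher by 1.09 ± 0.05, and Pparg, the receptor that the drug activates, by 0.82 ± 0.17 (adjusted p = 0.0104). Pparg lost its call without treated replicate 1 (0.72) or untreated replicate 2 (0.63). Of the 20 tested genes of lipogenesis and triglyceride synthesis, 12 rose, 4 fell and 4 did not pass (13 higher and 5 lower adjusted over the list alone). Lipogenesis and triglyceride synthesis had a median log2 difference of 0.67, with a camera adjusted p = 4.91e-04, and adjusted p = 0.207 with an estimated correlation. Fasn, fatty acid synthase, rose by 1.73 ± 0.07, while Acacb (-0.43), Dgat2 (-0.56), Gpam (-0.23) and Me1 (-0.20) of that list fell. Me1 lost its call with spike-in scaling (-0.097) and without treated replicate 1 (-0.23), treated replicate 2 (-0.18), untreated replicate 1 (-0.24) or untreated replicate 2 (-0.17). Of the 11 tested liver X receptor targets and cholesterol efflux genes, 7 rose, 0 fell and 4 did not pass (7 higher and 0 lower adjusted over the list alone). Liver X receptor targets and cholesterol efflux had a median log2 difference of 0.49, with a camera adjusted p = 4.29e-04, and adjusted p = 0.149 with an estimated correlation. The cholesterol exporter Abca1 rose by 1.04 ± 0.07 and Apoc1, an apolipoprotein, by 2.43 ± 0.21.

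Of the 13 tested brown adipocyte markers, 6 rose, 1 fell and 6 did not pass (7 higher and 1 lower adjusted over the list alone), Ppargc1a being lower (-0.58). Brown adipocyte markers had a median log2 difference of 0.47, with a camera adjusted p = 9.41e-04, and adjusted p = 0.262 with an estimated correlation. This call was lost with trimmed-mean scaling and with spike-in scaling. Otop1 rose by 3.80 ± 0.42 and Elovl3, a fatty acid elongase of brown fat, by 2.89 ± 0.30. Of the 15 tested markers of neighbouring organs (lung, thymus and mesothelium), 8 rose, 0 fell and 7 did not pass (8 higher and 1 lower adjusted over the list alone). Neighbouring organ markers had a median log2 difference of 0.74, with a camera adjusted p = 4.91e-04, and adjusted p = 0.149 with an estimated correlation. The secretoglobin Scgb3a2 rose by 6.67 ± 0.42 and the airway cytochrome Cyp2f2 by 5.88 ± 0.26. Of the 14 tested T and B lymphocyte markers, 6 rose, 1 fell and 7 did not pass (8 higher and 1 lower adjusted over the list alone), Cd8a being lower (-1.16). T and B lymphocyte markers had a median log2 difference of 0.49, with a camera adjusted p = 0.00386, and adjusted p = 0.172 with an estimated correlation. The immunoglobulin genes Ighm and Jchain rose by 3.52 ± 0.23 and 3.09 ± 0.26 in turn. Of 6 other Ighm probe sets, those at 6.10 and 1.28 passed as higher, and those at 0.52, 0.11, 0.67 and -0.17 did not pass. Cd8a lost its call with the mean of its probe sets (-0.79).

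Of the 14 tested atrial markers, 10 rose, 2 fell and 2 did not pass (11 higher and 2 lower adjusted over the list alone). Atrial markers had a median log2 difference of 1.07, with a camera adjusted p = 3e-05, and adjusted p = 0.149 with an estimated correlation. Sln, an inhibitor of the calcium pump in atria, rose by 2.17 ± 0.06, and the atrial myosin light chains Myl4 and Myl7 by 1.65 ± 0.04 and 1.51 ± 0.03. The members that fell were the potassium channels Kcna5 and Kcnk3 (-0.19). Nppa, the atrial natriuretic peptide, was higher by 0.77 ± 0.03, but the sign turned with array medians centred (-0.064) and with trimmed-mean scaling (-0.029). Among the ventricular stress genes, Myh7, the slow myosin heavy chain, fell by 1.0 ± 0.07 on the log2 scale, and Nppb differed by -0.12 ± 0.04 (adjusted p = 0.0860), which did not pass, although it passed as lower with trimmed-mean scaling (-0.60), spike-in scaling (-0.42) and array medians centred (-0.64), and without treated replicate 2 (-0.16). Acta1, skeletal alpha-actin, gave 0.26 ± 0.04 and turned to -0.30 with array medians centred, -0.26 with trimmed-mean scaling and -0.085 with spike-in scaling. The fatty acid transporter Cd36 gave 0.40 ± 0.04, was not called with spike-in scaling, and turned to -0.21 and -0.17 with array medians centred and trimmed-mean scaling. With quantile normalization its other probe sets passed as higher (0.79 and 0.38). Of the 36 tested extracellular matrix and fibrosis genes, 21 rose, 2 fell and 13 did not pass (22 higher and 3 lower adjusted over the list alone), with Col15a1 (-0.49) and Thbs1 (-0.87) lower. Extracellular matrix and fibrosis had a median log2 difference of 0.44, with a camera adjusted p = 7.24e-07, and adjusted p = 0.149 with an estimated correlation. Beside them, 9 of 17 fibroblast markers and 12 of 17 white adipocyte markers rose and 1 of each fell (adjusted p = 0.207 and 0.149 with an estimated correlation), so matrix values do not tell the heart's own matrix from that of attached tissue. Postn, a matrix protein of activated fibroblasts, rose by 1.21 ± 0.07, the proteoglycan Bgn by 0.80 ± 0.04 and the collagen Col3a1 by 0.56 ± 0.04. Kcnk3 lost its call with spike-in scaling (-0.10) or the mean of its probe sets (-0.16) and without treated replicate 1 (-0.18), untreated replicate 1 (-0.20) or untreated replicate 2 (-0.18). Col15a1 lost its call with trimmed-mean scaling (-0.39) or spike-in scaling (-0.22) and without treated replicate 1 (-0.35), untreated replicate 1 (-0.38) or untreated replicate 2 (-0.60). Thbs1 lost its call with spike-in scaling (-0.58) and without treated replicate 2 (-0.74) or untreated replicate 2 (-0.79).

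Of the 16 tested heat shock proteins, 1 rose, 12 fell and 3 did not pass (2 higher and 13 lower adjusted over the list alone). Heat shock proteins had a median log2 difference of -0.58, with a camera adjusted p = 2.58e-06, and adjusted p = 0.149 with an estimated correlation. The co-chaperones Hsph1 and Dnaja1 changed by -1.43 ± 0.06 and -1.29 ± 0.06. Hspb6, the member that rose (0.22), turned to -0.53 with array medians centred, -0.49 with trimmed-mean scaling and -0.31 with spike-in scaling. Of the 23 tested genes of the unfolded protein response, 1 rose, 14 fell and 8 did not pass (1 higher and 17 lower adjusted over the list alone), Asns being higher (0.77). Unfolded protein response genes had a median log2 difference of -0.35, with a camera adjusted p = 1.94e-05, and adjusted p = 0.149 with an estimated correlation. The chaperone Hspa5 changed by -0.67 ± 0.04 and the secreted stress protein Manf by -1.29 ± 0.07. Of the 18 tested genes of mitochondrial fatty acid oxidation, 1 rose, 12 fell and 5 did not pass (1 higher and 14 lower adjusted over the list alone). Mitochondrial fatty acid oxidation had a median log2 difference of -0.21, with a camera adjusted p = 0.00175, and adjusted p = 0.334 with an estimated correlation. Hadha changed by -0.36 ± 0.04, Eci1 by -0.48 ± 0.04 and Cpt2 by -0.39 ± 0.04. Asns lost its call without treated replicate 2 (0.51), untreated replicate 1 (0.74) or untreated replicate 2 (0.81). Cpt2 lost its call with the mean of its probe sets (-0.31). Acadm, the member that rose (0.33), turned to -0.44, -0.40 and -0.22 with array medians centred, trimmed-mean and spike-in scaling.

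Of the 17 tested glucocorticoid response genes, 1 rose, 11 fell and 5 did not pass (2 higher and 12 lower adjusted over the list alone), Sgk1 being higher (0.66). Glucocorticoid response had a median log2 difference of -0.37, with a camera adjusted p = 0.00363, and adjusted p = 0.262 with an estimated correlation. Klf15, a regulator of cardiac lipid use, changed by -0.78 ± 0.08 and Pdk4, the kinase that inhibits pyruvate dehydrogenase, by -0.58 ± 0.04. Angptl4, a PPAR target that inhibits lipoprotein lipase, rose by 4.88 ± 0.21, and the mitochondrial carrier Ucp3 changed by -0.62 ± 0.15. Ucp3 lost its call with spike-in scaling (-0.33) and without treated replicate 1 (-0.66), treated replicate 2 (-0.57) or untreated replicate 1 (-0.37). Of the 28 tested PPAR target genes of lipid handling, 6 rose, 14 fell and 8 did not pass (7 higher and 15 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.236, and adjusted p = 0.442 with an estimated correlation), its median (-0.20) and mean (0.050) differing in sign. Of the 24 tested interferon response genes, 11 rose, 0 fell and 13 did not pass (12 higher and 1 lower adjusted over the list alone). Interferon response had a median log2 difference of 0.43, with a camera adjusted p = 1.86e-04, and adjusted p = 0.153 with an estimated correlation. Gbp2, an interferon-induced GTPase, rose by 0.91 ± 0.10. Of the 5 tested red blood cell markers, 0 rose, 2 fell and 3 did not pass (0 higher and 3 lower adjusted over the list alone), these being Alas2 (-1.46) and Hbb-b2 (-1.06). Red blood cell markers had a median log2 difference of -0.65, with a camera adjusted p = 0.0312, and adjusted p = 0.262 with an estimated correlation. That list's call was lost without treated replicate 2 (median -0.46), untreated apoE-deficient replicate 2 (-0.42) or either B6 array (-0.65 each), and with no filter on dim probe sets (-0.34). Hbb-b2 lost its call without treated replicate 2 (-1.0). Cell cycle, peroxisomal fatty acid oxidation and fibroblast lists also shifted up with the preset correlation, with adjusted p = 0.172, 0.207 and 0.207 with an estimated correlation. The fibroblast call was lost with trimmed-mean and spike-in scaling and without untreated replicate 2 (median 0.23), and the peroxisomal call with the mean of the probe sets of a gene (0.17) or trimmed-mean scaling (0.13).

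Very bright genes of contraction depended on scaling. Pln, phospholamban, gave 0.22 ± 0.03 and turned to -0.63, -0.59 and -0.41 with array medians centred, trimmed-mean and spike-in scaling. Atp2a2, the calcium pump of the sarcoplasmic reticulum, gave -0.094 ± 0.04, which did not pass, against -0.95, -0.91 and -0.73, which did, in these settings. Myh6, the fast myosin heavy chain, changed by -0.12 ± 0.03 and turned to 0.017 with the mean of its probe sets. Pebp1, an inhibitor of Raf kinase, changed by -0.16 ± 0.03. Of the other probe sets of Pln, 1 passed as higher (0.18) and 1 as lower (-0.12). Of those of Atp2a2, 2 passed as lower (-0.36 and -0.16), 1 as higher (0.60) and 1 did not pass (-0.25). Myh6 lost its call without treated replicate 1 (-0.096), untreated replicate 1 (-0.12) or untreated replicate 2 (-0.12). Pebp1 lost its call without untreated replicate 2 (-0.14).

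In this comparison 5355 of 27022 tested probe sets passed, 2703 higher and 2652 lower, of which 632 higher and 170 lower exceeded 2-fold. Of 13236 genes, 1508 were higher and 1627 lower. Calls were 50.5% higher here, 38.0% with array medians centred, 79.6% with spike-in scaling and 99.9% with unscaled values. Of 41 lists, 12 shifted up and 5 down with the preset correlation, 0 passed with an estimated correlation (camera, lowest adjusted p = 0.149; 10 at an unadjusted p under 0.05), and 35 passed with fry. The count fell to 1653 without the intensity trend in limma's variance model and to 2944 without treated replicate 1. The Fen1 probe set (-2.42 ± 0.22) was not matched by the other probe set of that gene, at 0.11.

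**Figure D2:**
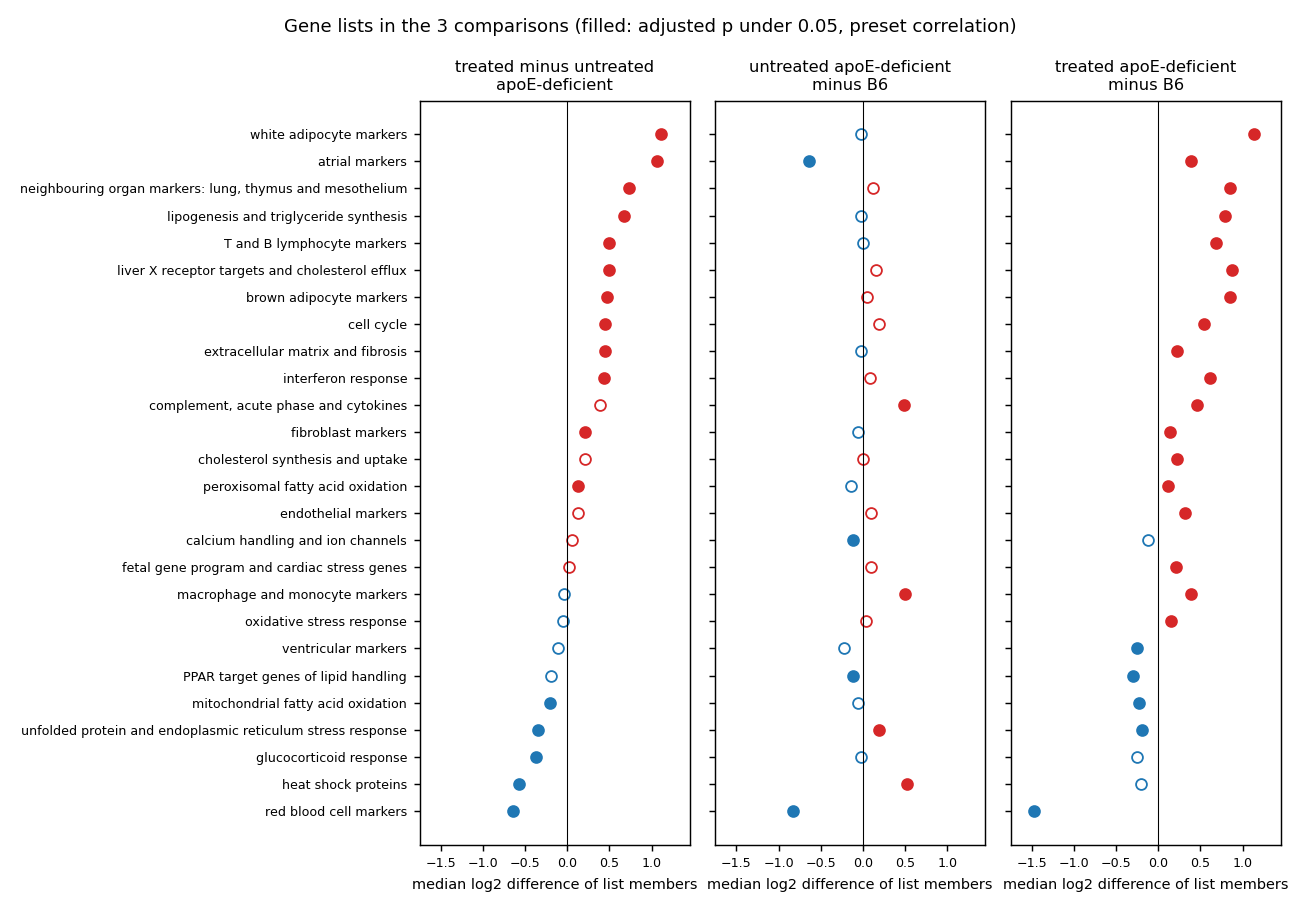
Median log2 difference of the tested members (horizontal axis) of each gene list that passed in at least 1 comparison, in the 3 comparisons. Red is above 0 and blue below, and filled points passed at an adjusted p under 0.05 with the preset correlation. White adipocyte markers had a median of 1.11 in the first panel and -0.02 in the second, and heat shock proteins -0.58 and 0.52. The first and second panels share the untreated apoE-deficient arrays with opposite sign, so mirrored values are not independent. With spike-in scaling the medians of unfolded protein genes in the third panel (-0.19) and of PPAR targets and calcium handling genes in the second (-0.11 and -0.12) turned to 0.16, 0.13 and 0.10.

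The second comparison set untreated apoE-deficient hearts against B6 hearts. It uses the same untreated apoE-deficient arrays as the first, with the opposite sign. Anything particular to these arrays gives opposite values in the first and second comparisons, so such values are not independent evidence. Of 16 heat shock proteins 14 rose in the apoE-deficient hearts (adjusted p = 0.162 with an estimated correlation), Hspa1a by 2.94 ± 0.10 (adjusted p = 1.91e-06) and Hspa1b by 2.64 ± 0.10. Of 26 macrophage and monocyte markers 13 rose, 1 fell and 12 did not pass (adjusted p = 0.162 with an estimated correlation). Those that rose included the complement gene C1qb by 0.79 ± 0.05 and the lysozyme Lyz2 by 0.58 ± 0.04. Acp5, an acid phosphatase of macrophages and osteoclasts, differed by 2.37 ± 0.23, the orphan receptor Nr4a3 by 2.38 ± 0.27 and the carboxypeptidase-like gene Cpxm2 by 1.90 ± 0.07. The Nr4a3 value was not matched by the other probe set of that gene, at 0.21, which did not pass. The other Cpxm2 probe set passed as higher (1.09). Lower genes included the metabolic PPAR targets Pdk4 (-1.05 ± 0.04) and Angptl4 (-1.81 ± 0.21), and Ucp3 (-1.21 ± 0.15).

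Of the 16 tested heat shock proteins, 14 rose, 0 fell and 2 did not pass (14 higher and 0 lower adjusted over the list alone). Heat shock proteins had a median log2 difference of 0.52, with a camera adjusted p = 4.29e-11, and adjusted p = 0.162 with an estimated correlation. Hsph1 rose by 1.17 ± 0.06 and Hsp90aa1 by 0.94 ± 0.05. Of the 23 tested genes of the unfolded protein response, 5 rose, 0 fell and 18 did not pass (10 higher and 2 lower adjusted over the list alone), these being Atf3 (1.31), Atf4 (0.59), Creld2 (0.68), Hyou1 (0.47) and Manf (0.65). Unfolded protein response genes had a median log2 difference of 0.20, with a camera adjusted p = 0.00202, and adjusted p = 0.276 with an estimated correlation. Atf4 lost its call with the mean of its probe sets (0.23). Hyou1 lost its call with trimmed-mean scaling (0.42) or the mean of its probe sets (0.34) and without treated replicate 1 (0.47), treated replicate 2 (0.47), untreated replicate 1 (0.58), untreated replicate 2 (0.37), B6 replicate 1 (0.49) or B6 replicate 2 (0.46). Of the 26 tested macrophage and monocyte markers, 13 rose, 1 fell and 12 did not pass (16 higher and 1 lower adjusted over the list alone), Csf1r being lower (-0.26). Macrophage and monocyte markers had a median log2 difference of 0.51, with a camera adjusted p = 2.92e-07, and adjusted p = 0.162 with an estimated correlation. Csf1r lost its call with array medians centred (-0.19), trimmed-mean scaling (-0.22), spike-in scaling (-0.082) or the mean of its probe sets (-0.15) and without untreated replicate 1 (-0.23), untreated replicate 2 (-0.28) or B6 replicate 2 (-0.20). Of the 20 tested complement, acute phase and cytokine genes, 7 rose, 0 fell and 13 did not pass (11 higher and 0 lower adjusted over the list alone). Complement, acute phase and cytokines had a median log2 difference of 0.49, with a camera adjusted p = 3.68e-04, and adjusted p = 0.267 with an estimated correlation. The chemokine Ccl8 rose by 0.97 ± 0.13. Among 11 tested liver X receptor targets and cholesterol efflux genes, 4 rose, 1 fell and 6 did not pass (5 higher and 2 lower adjusted over the list alone). That list did not pass (camera adjusted p = 0.268, and adjusted p = 0.451 with an estimated correlation), its median (0.16) and mean (-0.35) differing in sign. The member that fell was Apoe, whose loss is the genotype itself and which pulls the mean down. The sign split thus does not describe the other members. Abca1 rose by 0.62 ± 0.07 and Abcg1 by 0.78 ± 0.10. Their other probe sets, at 0.65 and 0.34 (Abca1) and 0.72 (Abcg1), did not pass.

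Of the 14 tested atrial markers, 1 rose, 8 fell and 5 did not pass (1 higher and 11 lower adjusted over the list alone), Clu being higher (0.19). Atrial markers had a median log2 difference of -0.64, with a camera adjusted p = 4.39e-06, and adjusted p = 0.167 with an estimated correlation. Sln changed by -1.33 ± 0.06, Myl7 by -1.0 ± 0.03, Myl4 by -0.98 ± 0.04 and Nppa by -0.53 ± 0.03. The stress genes Nppb and Acta1 were higher, by 0.56 ± 0.04 and 0.75 ± 0.04, and Myh7 differed by 0.21 ± 0.07, which did not pass, although it passed as higher with array medians centred (0.29) and spike-in scaling (0.39). Clu lost its call without untreated replicate 1 (0.19), B6 replicate 1 (0.19) or B6 replicate 2 (0.19). Myl4 lost its call with the mean of its probe sets (-0.63). Of the 28 tested PPAR target genes of lipid handling, 1 rose, 9 fell and 18 did not pass (3 higher and 16 lower adjusted over the list alone), Slc25a20 being higher (0.33) although another probe set of that gene passed as lower (-0.22). PPAR target genes of lipid handling had a median log2 difference of -0.11, with a camera adjusted p = 0.00202, and adjusted p = 0.276 with an estimated correlation. Txnip, an inhibitor of thioredoxin, changed by -1.02 ± 0.04. Of the 20 tested genes of calcium handling and ion channels, 0 rose, 7 fell and 13 did not pass (0 higher and 9 lower adjusted over the list alone). Calcium handling and ion channels had a median log2 difference of -0.12, with a camera adjusted p = 0.00277, and adjusted p = 0.267 with an estimated correlation. The calls of these last lists were lost with trimmed-mean and with spike-in scaling, and with spike-in scaling their medians turned to 0.13 (PPAR targets) and 0.10 (calcium handling). Slc25a20 lost its call with the mean of its probe sets (0.055) and without untreated replicate 1 (0.38), untreated replicate 2 (0.28) or B6 replicate 1 (0.25). Of the 5 tested red blood cell markers, 0 rose, 4 fell and 1 did not pass (0 higher and 4 lower adjusted over the list alone), namely Alas2 (-1.20), Bpgm (-0.68), Hbb-b2 (-1.0) and Slc25a37 (-0.73). Red blood cell markers had a median log2 difference of -0.82, with a camera adjusted p = 0.00202, and adjusted p = 0.276 with an estimated correlation. Alas2 lost its call without B6 replicate 2 (-1.15). Bpgm lost its call with no pseudocount (-0.70), spike-in scaling (-0.60) or the replicate number as a block (-0.68) and without treated replicate 1 (-0.68), untreated replicate 1 (-0.42), B6 replicate 1 (-0.59) or B6 replicate 2 (-0.77). Hbb-b2 lost its call with the mean of its probe sets (-0.51) and without untreated replicate 1 (-0.72), B6 replicate 1 (-0.99) or B6 replicate 2 (-1.01). Slc25a37 lost its call without untreated replicate 2 (-0.68), B6 replicate 1 (-0.76) or B6 replicate 2 (-0.70).

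Of the 17 tested white adipocyte markers, 1 rose, 4 fell and 12 did not pass (2 higher and 4 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.568), its median (-0.024) and mean (0.061) differing in sign. The member that rose was Acp5, described above as a gene of macrophages and osteoclasts, so its rise does not speak for fat cells. It also lifts the list's mean. Those that fell were Adipoq (-0.86 ± 0.10), Car3 (-0.83 ± 0.06), Cidec (-1.0 ± 0.18) and the lipase Lipe (-0.38 ± 0.10). Scd1 changed by -0.61 ± 0.07 and Fasn by -0.33 ± 0.07. Scd1 lost its call with the mean of its probe sets (-0.38). Fasn lost its call with spike-in scaling (-0.24) and without untreated replicate 1 (-0.32), untreated replicate 2 (-0.33), B6 replicate 1 (-0.36) or B6 replicate 2 (-0.29). Cidec lost its call without treated replicate 1 (-1.0), treated replicate 2 (-1.0) or B6 replicate 2 (-0.97). Lipe lost its call with no pseudocount (-0.39), spike-in scaling (-0.30) or the replicate number as a block (-0.38) and without treated replicate 1 (-0.38), treated replicate 2 (-0.38), untreated replicate 1 (-0.29), untreated replicate 2 (-0.47), B6 replicate 1 (-0.28) or B6 replicate 2 (-0.48).

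Of the bright panel genes, Pln (-0.07 ± 0.03), Atp2a2 (-0.081 ± 0.04), Myh6 (0.074 ± 0.03) and Pebp1 (0.07 ± 0.03) did not pass, although another Pln probe set passed as lower (-0.18). Myh6 passed with spike-in scaling (0.29), Pebp1 with array medians centred (0.23) and spike-in scaling (0.34), and Pln with the mean of its probe sets (-0.095).

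In this comparison 1909 probe sets passed, 856 higher and 1053 lower, with 99 and 164 beyond 2-fold. Of 13236 genes, 510 were higher and 617 lower. Calls were 44.8% higher here, 58.5% with array medians centred, 80.9% with spike-in scaling and 4.65% with unscaled values. Of 41 lists, 4 shifted up and 4 down with the preset correlation, 0 with an estimated correlation (camera, lowest adjusted p = 0.162; 7 at an unadjusted p under 0.05), and 26 passed with fry. The count was 10 without the intensity trend, and 857, 968, 653 and 614 without untreated apoE-deficient replicate 1 or 2 or B6 replicate 1 or 2. Fen1 (2.23 ± 0.22) was not matched by its other probe set, at -0.13, and the weak lower genes Igf2bp1 (-2.07 ± 0.32) and Slc26a11 (-2.03 ± 0.29) lost their calls without B6 replicate 1 (-2.12 and -1.74), Igf2bp1 also without B6 replicate 2 (-2.02).

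The third comparison set treated apoE-deficient hearts against B6 hearts, so genotype and drug differ together. The treated hearts had higher Bpifa1 by 8.57 ± 0.25, Ucp1 by 7.62 ± 0.39, Scgb1a1 by 7.45 ± 0.36, Scgb3a2 by 6.74 ± 0.42 and Cyp2f2 by 6.36 ± 0.26. Adipoq was higher by 4.23 ± 0.10 and Cidec by 3.93 ± 0.18, values that, like that of Ucp1, do not tell heart muscle from attached fat. Beside Apoe, the lowest values belonged to Aqp1 (-2.80 ± 0.05), the heme synthesis enzyme Alas2 (-2.66 ± 0.18) and Kcna5 (-2.29 ± 0.10). Pdk4 changed by -1.62 ± 0.04 and Ucp3 by -1.83 ± 0.15, while Angptl4 rose by 3.07 ± 0.21.

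Of the 17 tested white adipocyte markers, 14 rose, 1 fell and 2 did not pass (14 higher and 1 lower adjusted over the list alone), Plin4 being lower (-0.57). White adipocyte markers had a median log2 difference of 1.14, with a camera adjusted p = 2.67e-11, and adjusted p = 0.113 with an estimated correlation. Scd1 rose by 2.29 ± 0.07, Fasn by 1.40 ± 0.07 and Pparg by 0.78 ± 0.17. Pparg lost its call without treated replicate 1 (0.68) or B6 replicate 2 (0.63). Of the 15 tested markers of neighbouring organs, 8 rose, 0 fell and 7 did not pass (10 higher and 0 lower adjusted over the list alone). Neighbouring organ markers had a median log2 difference of 0.86, with a camera adjusted p = 8.41e-06, and adjusted p = 0.113 with an estimated correlation. Of the 24 tested interferon response genes, 13 rose, 2 fell and 9 did not pass (15 higher and 2 lower adjusted over the list alone). Interferon response had a median log2 difference of 0.61, with a camera adjusted p = 2.54e-07, and adjusted p = 0.113 with an estimated correlation. Gbp6 rose by 1.19 ± 0.08 and Ifit3 by 1.14 ± 0.10. Iigp1 (-0.27) and Rsad2 (-0.25) were the lower members, and with spike-in scaling they turned to 0.034 and 0.082, and Iigp1 to 0.044 with the mean of its probe sets. Iigp1 lost its call without treated replicate 1 (-0.21), B6 replicate 1 (-0.26) or B6 replicate 2 (-0.27). Rsad2 lost its call with the mean of its probe sets (-0.11) and without treated replicate 1 (-0.26), treated replicate 2 (-0.23), B6 replicate 1 (-0.27) or B6 replicate 2 (-0.22). Of the 26 tested macrophage and monocyte markers, 14 rose, 0 fell and 12 did not pass (15 higher and 0 lower adjusted over the list alone). Macrophage and monocyte markers had a median log2 difference of 0.39, with a camera adjusted p = 3.51e-07, and adjusted p = 0.113 with an estimated correlation. Gpnmb, a gene of lipid-laden macrophages, rose by 2.30 ± 0.19 and Lgals3 by 2.26 ± 0.11. Of the 20 tested complement, acute phase and cytokine genes, 10 rose, 0 fell and 10 did not pass (12 higher and 0 lower adjusted over the list alone). Complement, acute phase and cytokines had a median log2 difference of 0.46, with a camera adjusted p = 1.34e-04, and adjusted p = 0.142 with an estimated correlation. Ccl8 rose by 2.59 ± 0.13 and the acute phase gene Serpina3n by 2.34 ± 0.23.

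Of the 36 tested extracellular matrix and fibrosis genes, 17 rose, 3 fell and 16 did not pass (19 higher and 3 lower adjusted over the list alone), Col15a1 (-0.50), Col4a1 (-0.36) and Lum (-0.28) being lower. Extracellular matrix and fibrosis had a median log2 difference of 0.22, with a camera adjusted p = 8.41e-06, and adjusted p = 0.113 with an estimated correlation. Beside them, 8 of 17 fibroblast markers and 14 of 17 white adipocyte markers rose and 1 of each fell (adjusted p = 0.165 and 0.113 with an estimated correlation), so matrix values do not tell the heart's own matrix from that of attached tissue. Postn rose by 1.44 ± 0.07 and Bgn by 0.84 ± 0.04. Col15a1 lost its call with spike-in scaling (-0.14) and without treated replicate 1 (-0.36) or B6 replicate 2 (-0.36). Col4a1 lost its call with spike-in scaling (-0.14). Lum lost its call with spike-in scaling (-0.034) and without treated replicate 1 (-0.21), B6 replicate 1 (-0.29) or B6 replicate 2 (-0.27). Of the 18 tested genes of mitochondrial fatty acid oxidation, 1 rose, 13 fell and 4 did not pass (1 higher and 14 lower adjusted over the list alone). Mitochondrial fatty acid oxidation had a median log2 difference of -0.23, with a camera adjusted p = 2.68e-04, and adjusted p = 0.246 with an estimated correlation. Eci1 changed by -0.54 ± 0.04 and Cpt2 by -0.49 ± 0.04, and Acadm, the one higher (0.17), turned to -0.44, -0.43 and -0.11 with array medians centred, trimmed-mean and spike-in scaling. Acadm lost its call without treated replicate 1 (0.095), untreated replicate 1 (0.17), untreated replicate 2 (0.17), B6 replicate 1 (0.17) or B6 replicate 2 (0.17). Cpt2 lost its call with the mean of its probe sets (-0.15). Of the 28 tested PPAR target genes of lipid handling, 6 rose, 16 fell and 6 did not pass (7 higher and 17 lower adjusted over the list alone). PPAR target genes of lipid handling had a median log2 difference of -0.30, with a camera adjusted p = 0.00192, and adjusted p = 0.165 with an estimated correlation. Of the 23 tested genes of the unfolded protein response, 1 rose, 9 fell and 13 did not pass (1 higher and 10 lower adjusted over the list alone), Asns being higher (0.81). Unfolded protein response genes had a median log2 difference of -0.19, with a camera adjusted p = 0.00870, and adjusted p = 0.179 with an estimated correlation. With spike-in scaling the median of that list turned to 0.16 and the list passed as higher. Hspa5 changed by -0.59 ± 0.04. Asns lost its call without treated replicate 2 (0.54), B6 replicate 1 (0.83) or B6 replicate 2 (0.79). Of the 5 tested red blood cell markers, 0 rose, 4 fell and 1 did not pass (0 higher and 5 lower adjusted over the list alone), namely Alas2, Hbb-b2 (-2.06), Bpgm (-0.97) and Slc25a37 (-1.09). Red blood cell markers had a median log2 difference of -1.47, with a camera adjusted p = 2.89e-04, and adjusted p = 0.142 with an estimated correlation.

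Of the 14 tested atrial markers, 8 rose, 2 fell and 4 did not pass (9 higher and 2 lower adjusted over the list alone), Kcna5 and Kcnk3 (-0.20) being lower, and Kcnk3 turned to 0.066 with spike-in scaling. Atrial markers had a median log2 difference of 0.39, with a camera adjusted p = 0.00544, and adjusted p = 0.160 with an estimated correlation. The list was not called with trimmed-mean or spike-in scaling. Kcnk3 lost its call without treated replicate 1 (-0.18), B6 replicate 1 (-0.20) or B6 replicate 2 (-0.20). Myl4 rose by 0.66 ± 0.04. Myl4 lost its call with the mean of its probe sets (0.62). Myl7 gave 0.51 ± 0.03 and was not called with array medians centred (0.035) or trimmed-mean scaling (0.041). Nppa gave 0.24 ± 0.03 and turned to -0.49 with array medians centred, -0.48 with trimmed-mean scaling and -0.17 with spike-in scaling. Acta1 was higher by 1.01 ± 0.04 and Nppb by 0.44 ± 0.04, the Nppb call being lost with array medians centred and trimmed-mean scaling, and Myh7 changed by -0.78 ± 0.07. Of the 10 tested ventricular markers, 0 rose, 4 fell and 6 did not pass (0 higher and 5 lower adjusted over the list alone), namely Fhl2 (-0.36), Kcne1 (-1.38), Lbh (-0.35) and Myl2 (-0.32). Ventricular markers had a median log2 difference of -0.25, with a camera adjusted p = 0.0132, and adjusted p = 0.165 with an estimated correlation. Lbh lost its call with spike-in scaling (-0.11). Myl2 lost its call without B6 replicate 2 (-0.29). Also passing with the preset correlation were lists of lipogenesis, brown adipocytes, liver X receptor targets, cardiac stress genes, lymphocytes, fibroblasts, endothelium, cell cycle, peroxisomal oxidation, cholesterol synthesis and oxidative stress, all shifted up, with adjusted p from 0.124 to 0.186 with an estimated correlation. Several of these list calls were also lost elsewhere, at the medians given here. Those of brown adipocytes, cardiac stress genes, fibroblasts, endothelium, peroxisomal oxidation and oxidative stress were lost with trimmed-mean scaling (0.84, 0.19, 0.082, 0.32, 0.098 and 0.12) and with spike-in scaling (1.06, 0.50, 0.40, 0.63, 0.40 and 0.43). The cholesterol synthesis call was lost with the mean of the probe sets of a gene (0.25) or spike-in scaling (0.57) and without treated replicate 2 (0.17) or B6 replicate 2 (0.17). The endothelial call was also lost without B6 replicate 1 (0.34) and the peroxisomal call without B6 replicate 2 (0.13). The oxidative stress call was also lost with the mean of the probe sets of a gene (0.12), with no filter on dim probe sets (0.14), and without treated replicate 1 (0.18), untreated replicate 1 or 2 (0.15 each) or B6 replicate 1 (0.057).

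Pln gave 0.15 ± 0.03 and turned to -0.56, -0.55 and -0.24 with array medians centred, trimmed-mean and spike-in scaling, and to -0.0031 with the mean of its probe sets, of which another passed as lower (-0.15) and a further one did not pass (-0.0076). Atp2a2 changed by -0.17 ± 0.04, and of its other probe sets 2 passed as lower (-0.18 and -0.34) and 2 did not pass (-0.29 and 0.083). Pln lost its call without B6 replicate 1 (0.13). Atp2a2 lost its call without B6 replicate 2 (-0.13). Myh6 (-0.043 ± 0.03) and Pebp1 (-0.086 ± 0.03) did not pass, but passed with array medians centred (-0.79 and -0.33) and trimmed-mean scaling (-0.79 and -0.32), Myh6 also with spike-in scaling (-0.47) and Pebp1 with the mean of its probe sets (-0.12).

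In this comparison 4066 probe sets passed, 2017 higher and 2049 lower, with 410 and 110 beyond 2-fold. Of 13236 genes, 1162 were higher and 1307 lower. Calls were 49.6% higher here, 41.4% with array medians centred, 92.5% with spike-in scaling and 99.7% with unscaled values. Of 41 lists, 18 shifted up and 5 down with the preset correlation, 0 with an estimated correlation (camera, lowest adjusted p = 0.113; 12 at an unadjusted p under 0.05), and 34 passed with fry. The count was 626 without the intensity trend, and 2289, 2618 and 2192 without treated replicate 1, B6 replicate 1 or B6 replicate 2.

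Both apoE-deficient groups were compared with the same B6 arrays. In both comparisons 309 probe sets were higher and 337 lower, where independent lists would share 63.9 and 79.8, while simulated unchanged groups against the same arrays, with no effects in them, shared 0.03 and 0.13 on average and at most 1 and 2 over 100 simulations. Another 219 probe sets passed in opposite directions. The log2 differences correlated with r = 0.302 across probe sets, which are not independent replicates, against 0.50 simulated, and their covariance was 0.0560 against 0.0354 simulated, a difference of 0.0207. The B6 arrays cannot be split with more than 1 array on each side, so part of the overlap above independent lists may come from the shared controls, and how large that part is was not measured. The overlap was 2 without the intensity trend and 298, 321, 264 and 221 without untreated apoE-deficient replicate 1 or 2 or B6 replicate 1 or 2.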

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

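The array carries control probe sets for mouse transcripts that enter none of the comparisons, and 3 differences among them stood above the B6 arrays after trimmed-mean scaling, where both arrays of a group lay at least 1.5-fold above both B6 arrays with a scaled signal of at least 100, a rule and a scaling chosen after the data were seen. The probe set for the B1 repeat, a short interspersed element present in many copies, was higher by 0.91 on the log2 scale on the treated arrays and by 0.75 on the untreated apoE-deficient arrays. With spike-in scaling these differences were 1.23 and 0.88, and with unscaled values 1.80 and 0.41. The 3' probe set for pyruvate carboxylase was higher by 0.92 on the treated arrays, by 1.23 with spike-in scaling and by 1.81 with unscaled values. With trimmed-mean scaling, the other pyruvate carboxylase probe sets gave 0.041 (5'), 0.14 and 0.75 (both middle) on the treated arrays. None of these met the rule. This rule looked for higher values alone. The 3 probe sets for 18S ribosomal RNA lay lower than B6 on the untreated apoE-deficient arrays, by log2 differences of -0.85 (3'), -1.01 (5') and -1.79 (middle), against -0.71, -0.87 and -1.65 with spike-in scaling and -1.18, -1.35 and -2.13 unscaled. On the treated arrays they gave -0.55, -0.41 and -0.48, against -0.24, -0.098 and -0.17 with spike-in scaling, and turned to 0.34, 0.48 and 0.41 unscaled. These lower values were not tested, and no explanation was tested.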

How the results depend on the processing

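Trimmed-mean and spike-in scaling, and quantile normalization in place of unscaled values, were chosen after the data were seen, and the cause of changes was not tested unless given. Named genes were rerun with other pseudocounts, array medians centred, trimmed-mean and spike-in scaling, the replicate block, the mean of a gene's probe sets and each array left out. Of these values, 1099, 584 and 734 kept direction and side of the threshold in the 3 comparisons, 65, 60 and 39 lost a call, 9, 6 and 6 gained one, and 23 and 14 reversed in the comparisons that hold the treated arrays. Of values of lists that passed, 209, 100 and 272 kept their calls, 29, 12 and 49 lost them and 0, 0 and 1 reversed. Neither tally holds the fit without the intensity trend, unscaled values, the 2-group fit or other thresholds, which were run for counts of probe sets alone. The tally of lists also leaves out array medians centred, with which passing lists were only counted. Without the intensity trend, counts of passing probe sets were 1653 (treated against untreated apoE-deficient), 10 (untreated apoE-deficient against B6) and 626 (treated against B6), and 2 passed in both comparisons against B6. Unscaled values gave 22739 and 18723 for the comparisons that hold the treated arrays, which are the brightest. Spike-in scaling gave 3039 and 7604 against B6, with 1452 in both. The pairwise 1.5-fold rule gave 1910, 915 and 1323, and an adjusted p under 0.10 gave 3179 for untreated apoE-deficient against B6 and 1041 in both. Leaving out 1 array gave 2944 to 4996, 614 to 1729 and 2192 to 4120, and 221 to 489 in both; the lone array of a group is assumed to vary like the others, and fewer arrays enter the fit. With an estimated correlation, where camera also takes the 3 residual degrees of freedom of the fit, 0, 0 and 0 lists passed. Fry passed 35 and 26 lists in the first comparisons, centred medians 27 and spike-in scaling 26 in the first, and trimmed-mean scaling 14 and spike-in scaling 15 in the second.

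With the replicate number as a block, 5344, 1937 and 4103 probe sets passed, against 5355, 1909 and 4066 without it; residuals of same-numbered arrays correlated between -0.006 and 0.033, so the arrays share only a number. Reversed values, with array medians centred, trimmed-mean and spike-in scaling in this order where each applies, were for treated against untreated apoE-deficient Nppa (-0.064 and -0.029), Acta1 (-0.30, -0.26 and -0.085), Cd36 (-0.21 and -0.17), Hspb6 (-0.53, -0.49 and -0.31), Pln (-0.63, -0.59 and -0.41), Acadm (-0.44, -0.40 and -0.22), Oxct1 (-0.47, -0.43 and -0.25) and Slc16a1 (-0.0094 with array medians centred), and with the mean of their probe sets Myh6 (0.017), Lyz1 (0.38) and C1qb (0.25). For treated against B6 they were Nppa (-0.49, -0.48 and -0.17), Pln (-0.56, -0.55 and -0.24) and Acadm (-0.44, -0.43 and -0.11), and with spike-in scaling Iigp1 (0.034), Rsad2 (0.082), Kcnk3 (0.066) and the median of the unfolded protein list (0.16). Iigp1 gave 0.044 and Pln -0.0031 with the mean of their probe sets. Signal over background limits dim genes, whose differences rest on the pseudocount.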

Other observations

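The tests of lung parenchyma, of array brightness for the airway genes, for the atrial genes against B6 and with scalings other than quantile normalization, of stress genes and of shared RNA were chosen after the results they measure were seen. In treated against untreated apoE-deficient hearts, many lists that did not pass as lists held members that passed in both directions, and the 4 given next were picked after their values were seen. Of the 26 tested macrophage and monocyte markers, 4 rose, 5 fell and 17 did not pass (4 higher and 6 lower adjusted over the list alone). That list had a camera adjusted p = 0.997, and adjusted p = 0.997 with an estimated correlation, and its median (-0.044) and mean (0.092) differed in sign. Gpnmb rose by 2.26 ± 0.19, Lgals3 by 1.82 ± 0.11, Mrc1 by 0.33 ± 0.07 and Csf1r by 0.25 ± 0.05, while Adgre1 changed by -0.61 ± 0.08, Fcer1g by -0.64 ± 0.11 and Tyrobp by -0.27 ± 0.08. Lyz1 (-0.15) and C1qb (-0.17) were lower, but turned to 0.38 and 0.25 with the mean of their probe sets. Another Lyz1 probe set (1.60) and the other C1qb probe sets (0.49 and 0.43) passed as higher, and a further Lyz1 probe set (-0.32) did not pass. Mrc1 lost its call without treated replicate 1 (0.32) or untreated replicate 1 (0.32). Csf1r lost its call with array medians centred (0.096), trimmed-mean scaling (0.14) or the mean of its probe sets (0.22) and without treated replicate 2 (0.22) or untreated replicate 1 (0.22). Tyrobp lost its call with spike-in scaling (-0.069) and without treated replicate 1 (-0.21), treated replicate 2 (-0.33), untreated replicate 1 (-0.24), untreated replicate 2 (-0.30) or B6 replicate 2 (-0.27). Lyz1 lost its call without treated replicate 2 (-0.13), untreated replicate 1 (-0.14) or untreated replicate 2 (-0.16). C1qb lost its call with spike-in scaling (-0.072) or the replicate number as a block (-0.17) and without treated replicate 1 (-0.14), treated replicate 2 (-0.20), untreated replicate 1 (-0.18), untreated replicate 2 (-0.16), B6 replicate 1 (-0.17) or B6 replicate 2 (-0.17).

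Of the 19 tested endothelial markers, 9 rose, 4 fell and 6 did not pass (10 higher and 4 lower adjusted over the list alone), with a camera adjusted p = 0.0740, and adjusted p = 0.262 with an estimated correlation. Kdr, a receptor for vascular growth factor, rose by 0.91 ± 0.06 and Gpihbp1, which anchors lipoprotein lipase on capillaries, by 0.67 ± 0.05, while the members that fell were Aqp1 (-3.0), Flt1 (-0.88), Nos3 (-0.48) and Tie1 (-0.41). The other Flt1 probe sets, at -0.24, -0.17 and -0.15, did not pass. Tie1 lost its call with spike-in scaling (-0.16) and without treated replicate 1 (-0.35). Of the 16 tested genes of ketone and branched-chain amino acid metabolism, 3 rose, 6 fell and 7 did not pass (3 higher and 9 lower adjusted over the list alone), with a camera adjusted p = 0.178, and adjusted p = 0.334 with an estimated correlation. The ketone enzyme Bdh1 rose by 0.61 ± 0.04, and the branched-chain amino acid enzymes Ivd and Bckdha changed by -0.77 ± 0.04 and -0.67 ± 0.04. The other members that rose, Oxct1 (0.29) and Slc16a1 (0.36), depended on scaling: Oxct1 turned to -0.47, -0.43 and -0.25 with array medians centred, trimmed-mean and spike-in scaling, and Slc16a1 to -0.0094 with array medians centred. Slc16a1 lost its call with trimmed-mean scaling (0.027), spike-in scaling (0.20) or the mean of its probe sets (0.30). Bdh1 was also higher in untreated apoE-deficient than in B6 hearts, by 1.03 ± 0.04. Of the 22 tested immediate early genes, 6 rose, 6 fell and 10 did not pass (7 higher and 6 lower adjusted over the list alone), with a camera adjusted p = 0.346, and adjusted p = 0.442 with an estimated correlation. Fos and Egr1 rose by 2.29 ± 0.14 and 1.93 ± 0.06, and Klf2 changed by -0.76 ± 0.05.

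Airway secretory transcripts in the treated hearts may come from airway tissue in the samples. Of 17 tested secretory markers 14 were higher than in B6. Their list lies outside those fixed beforehand and holds genes already named as high, among them Bpifa1, Scgb1a1, Scgb3a2 and Cyp2f2. Scgb1a1, Bpifa1 and Reg3g lay below the filter level of 4.99 on the untreated apoE-deficient arrays (4.29, 4.16 and 3.76). They also did on the B6 arrays (4.39, 4.24 and 4.09). Such genes were tested only because the treated arrays raised their mean, so the count is not evidence for airway tissue. Of 21 ciliated markers on the array 6 were bright enough to test, 0 of them higher and 1 (Mlf1) lower, and of 15 general epithelial genes 4 were higher (Krt7, Krt8, Krt18 and Cldn3) and 1 (Cxadr) lower. Together they had a median difference of 0.31 (95% bootstrap interval 0.066 to 0.90 over 21 genes), between the bounds set in advance, so airway tissue cannot be told apart from another source. Lung parenchyma cannot be told apart either: the 8 tested alveolar markers had a median difference from B6 of 0.27 (interval -0.33 to 0.86), but 5 of the 8 lay within 1 log2 unit of the lowest tested level and Hopx (-0.60) is bright in B6 hearts, so a low median excludes nothing. Brighter arrays do not account for the secretory genes, whose lowest median over 4 scalings was 2.48, and the treatment stays open as an untested biological hypothesis.

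Of 14 tested atrial markers 10 were lowest in untreated apoE-deficient and highest in treated hearts with quantile and with spike-in scaling and 9 with trimmed-mean scaling or array medians centred, Nppa having that order with quantile normalization alone, Nr2f2 with spike-in scaling alone and Kcna5, Kcnk3 and Clu with none of them, and a different share of atrial tissue is a candidate explanation. Of 10 further atrial genes 20% had that order (exact 95% interval 2.52 to 55.6%, against 18.9% of all genes) and 50% with spike-in scaling. The first value met the bound of at most 25% set in advance against atrial tissue, but its interval passes the 50% set in advance for it. That condition on the interval was required only after the value was seen, and on that ground atrial tissue cannot be told apart from another cause. Among the 10 genes, 4 passed as lower and 0 as higher in untreated apoE-deficient against B6 hearts. For treated against untreated apoE-deficient hearts 3 passed as higher and 0 as lower, and for treated against B6 hearts 2 as higher and 1 as lower. The stress genes did not share the atrial order: 0 of Nppb, Acta1, Ankrd1 and Myh7 had it with any of the 4 scalings. Of these 4, 3 passed in a direction against it, a condition also added after the result was seen. The test was chosen when these values were known, so its outcome was fixed. It shows that these 4 genes moved otherwise than the atrial markers and cannot decide on re-expression with stress. With each of 4 scalings the atrial list's median lay beyond 100% of 10000 random lists matched on level in broad bins. It lay above them for treated against untreated apoE-deficient hearts (medians 0.85 to 1.09). For untreated apoE-deficient against B6 hearts it lay below them (-0.72 to -0.58). For these parts of the order, this argues against an effect of brightness that depends on level alone. The atrial list had already passed against other genes in both comparisons, so a place beyond these random lists was likely beforehand. For treated above B6 hearts brightness cannot be told apart from another cause, since the median exceeded at least 99.5% of such lists with each scaling but the list's call was lost with trimmed-mean (0.15, adjusted p = 0.499) and spike-in scaling (0.46, adjusted p = 0.642), and the treatment stays open, untested.

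The treated arrays were close (r = 0.987, median absolute log2 difference 0.136), and whether shared RNA lay behind both was not settled. The untreated apoE-deficient arrays (r = 0.968, 0.189) correlated hardly better than the first of them with the first B6 array (0.966, 0.249). Over 29 genes of other tissues, the median absolute log2 difference between the treated arrays was 0.0733. The 95th percentile of random lists matched on level was 0.110. The 29 genes had been kept because they passed as higher in treated than in B6 hearts, by over 1 on the log2 scale. Such a call favours genes on which the treated arrays lie close, so the test cannot decide whether RNA was shared. The value also rests on 1 pair of arrays, and equal amounts of other tissue in separate animals would give the same value. No biological explanation was tested.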
